A study of Rattus norvegicus with 3 samples.

How the data were processed

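The series holds ChIP-seq of germ cells from testes of adult Holtzman rats aged 75 to 90 days, with 1 library each for an antibody to ERα, an antibody to ERβ and a mock immunoprecipitation with anti-rabbit IgG. Per the labels' protocols, seminiferous tubules were digested with trypsin and DNase, interstitial cells were lysed in hypotonic buffer and Sertoli cells were held back by mesh filtering, so the chromatin comes from enriched and not pure germ cells. Libraries were made from very small DNA amounts and sequenced as paired ends on an Illumina instrument, per the labels' protocols.

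Each library has 1 deposited peak list with chromosome, start, end, peak name and a score. The authors' score is a number per peak with no unit given in the lists. It was used to describe, rank or filter the peaks of each list. Some comparisons between lists used peaks filtered at a common score limit, and scores at the same locus are given side by side. A common limit need not mark the same signal in each list. Per the submitters' processing notes, reads were aligned with Bowtie 1.2. The deposited peak names begin with MACS, a peak caller. The caller's version, its cutoff, the use of a control library in calling and the genome build are not given in the sources used here. Whether the mock library was also the control in calling the receptor peaks is therefore unknown, and mock peaks at a receptor peak do not by themselves show how that receptor peak was scored. Read depth is unknown, so no value could be set against depth, and a longer list can reflect depth, antibody or calling. PCR duplicates and their removal are likewise not given in the sources used here.

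Lists were read line by line. The ERβ list had 12730 lines, of which 2 with a damaged position were left out. In the mock list, 1 line with a split score was kept without a score, and 2 lines with a misspelt peak name were kept. Starts were written 1-based. Peaks count as shared when they overlap by at least 1 bp. The overlap counts were checked with bedtools 2.31.1 and came out equal. Random placement drew 1000 positions for each peak of the first list within its own chromosome, from the start to the furthest peak end over all lists, because chromosome lengths were not used here. Gaps and unmappable sequence could not be left out of the placement. The two-sided permutation p has a smallest value of 0.001998, and Benjamini-Hochberg adjustment was over the 3 pairs.

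Shares carry 95% exact Clopper-Pearson intervals. The share of peaks on X was tested by an exact binomial test against its share of that sequence. Chromosomes and scaffolds with at least 20 peaks in the 2 lists together, and 1-Mb windows with at least 10, were compared between lists by Fisher's exact test with Benjamini-Hochberg adjustment at 0.05. Windows with 20 or more mock peaks numbered 77. Ratios of sharing have intervals from 2000 bootstrap draws of 1-Mb windows. The exact McNemar test compared how often strong peaks touched each of the other lists. Named regions followed a fixed rule, set in advance: the 10 highest regions shared by both receptors without a mock peak, by rank sum, and the 5 highest of each list. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

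The overlap test was tested on simulated lists with the real peak numbers. With no planted sharing, 5 of 40 draws for ERα with ERβ, 1 of 40 for ERα with mock and 0 of 40 for ERβ with mock had a p below 0.05. The rate for ERα with ERβ was above the nominal 0.05. With 200 planted shared peaks, the mean excess recovered was 198 for ERα with ERβ, 202 for ERα with mock and 195 for ERβ with mock. Simulated peaks had 1 fixed width and were spread evenly over autosomes and X, and fewer placements were drawn than for the real lists. The real lists are clustered, so the simulation does not show how the test behaves on them.

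The scaffold names are those of the Rnor_6.0 assembly. The gene table at hand belongs to another assembly, GRCr8, and on 6 of 21 chromosomes peaks lie more than 3 Mb beyond its last gene, so no gene was assigned to a peak. Planned tests of promoters, estrogen response elements, repeats and 15 gene lists were therefore not run. Alternatives chosen before the data were examined were a reciprocal overlap of 50%, a distance of 1 kb, the upper 50% of each list by score, placed chromosomes alone, a circular shift, 200 bp around midpoints and the mock share as the expectation for X. Alternatives chosen after the data were seen were placement within 250 kb, windows without dense mock peaks, a score of 50 or more or of 100 or more, and lists of 5347 peaks.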

Results

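Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where the estrogen receptors alpha (ERα) and beta (ERβ), nuclear receptors that bind DNA and regulate transcription in response to estrogens, sit on the genome of germ cells from adult Holtzman rat testes. A mock immunoprecipitation with anti-rabbit immunoglobulin G (IgG) was also sequenced and has its own peak list. Whether it served as the control in calling the receptor peaks is unknown. Each of the 3 antibodies has 1 library, so no value below carries a replicate error, and each test compares these 3 peak lists and not the antibodies as conditions. The lists hold positions and the authors' peak-caller score. Read depth is unknown, and intervals cover counting error only. The scaffold names are those of the Rnor_6.0 rat assembly, and positions are given as in the lists. Genes, exons and promoters at these positions were not analysed here.

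The ERα list was the shortest, with 5347 peaks covering 3373 kb. The ERβ list held 12728 peaks covering 7519 kb, and the mock list was the longest, with 15750 peaks covering 9266 kb. Peaks were narrow in all 3 lists, with median widths of 576 bp for ERα, 558 bp for ERβ and 568 bp for mock. Most peaks had low scores: the median score was 39.9 in the ERα list, 34.4 in the ERβ list and 35.0 in the mock list. The lists began near 30 but were filled differently above it. The 535 lowest-scoring ERα peaks spanned scores of 30.61 to 35.31. The 1273 lowest ERβ peaks spanned 30.01 to 30.56, and the 1575 lowest mock peaks 30 to 31.08. The ERβ and mock medians thus lay in a range that held few ERα peaks. Whether the lists had a common cutoff is unknown. Peaks with a score of 100 or more, called strong below, numbered 359 for ERα, 341 for ERβ and 308 for mock, so the lists differed in length mainly through peaks of low score. Below a score of 50 lay 4311 ERα, 11720 ERβ and 14480 mock peaks.

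The first comparison asked how far the regions found with the 2 receptor antibodies coincide with each other and with the mock list. Of the 5347 ERα peaks, 934 touched an ERβ peak, which is 17.5% (95% exact binomial interval 16.5 to 18.5), and 962 touched a mock peak, which is 18.0% (17.0 to 19.0). Of the 12728 ERβ peaks, 1191 touched a mock peak, or 9.36% (8.86 to 9.88), and 935 touched an ERα peak, or 7.35%. The larger part of each receptor list touched neither of the other lists: 4154 ERα peaks (77.7%) and 11315 ERβ peaks (88.9%). The mock list was alike, with 14282 of its peaks (90.7%) touching no receptor peak.

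All 3 pairs of lists coincided more often than random placement within the same chromosomes. The ERα and ERβ lists shared 23.9-fold more peaks than the mean of 39.1 in 1000 random placements, whose highest value was 64. The ERα and mock lists shared 19.9-fold more than the mean of 48.4, and the ERβ and mock lists 11.9-fold more than the mean of 100.3. Each two-sided permutation p was 0.001998, the smallest that 1000 placements can give, and remained so after Benjamini-Hochberg adjustment over the 3 pairs. When each peak was moved by no more than 250 kb, an alternative chosen after the data were seen, the excess fell to 8.01-fold for ERα with ERβ, 7.45-fold for ERα with mock and 5.76-fold for ERβ with mock. Both mock comparisons use the same mock list, so they are not independent.

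Sharing was concentrated among the peaks of highest score. In the top 10% of the ERα list, 91.2% of peaks touched an ERβ peak (exact binomial interval 88.5 to 93.5) and 89.7% touched a mock peak (86.8 to 92.2). In the top 10% of the ERβ list, 50.7% touched an ERα peak and 53.1% a mock peak. In the top 10% of the mock list, 39.9% touched an ERα peak and 43.3% an ERβ peak. These parts are not alike. The top 10% held 535 ERα peaks with scores from 70.35, 1273 ERβ peaks from 47.52 and 1575 mock peaks from 47.26. With the ERα list divided by score into 10 equal parts, each of the lowest 7 touched the mock list at 4.67% to 7.30% of its peaks. For scale, random placement of the whole ERα list gave a mean of 48.4 of 5347 peaks touching mock, a lower share than in any of these parts. Placement was not run for each part.

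**Figure D1:**
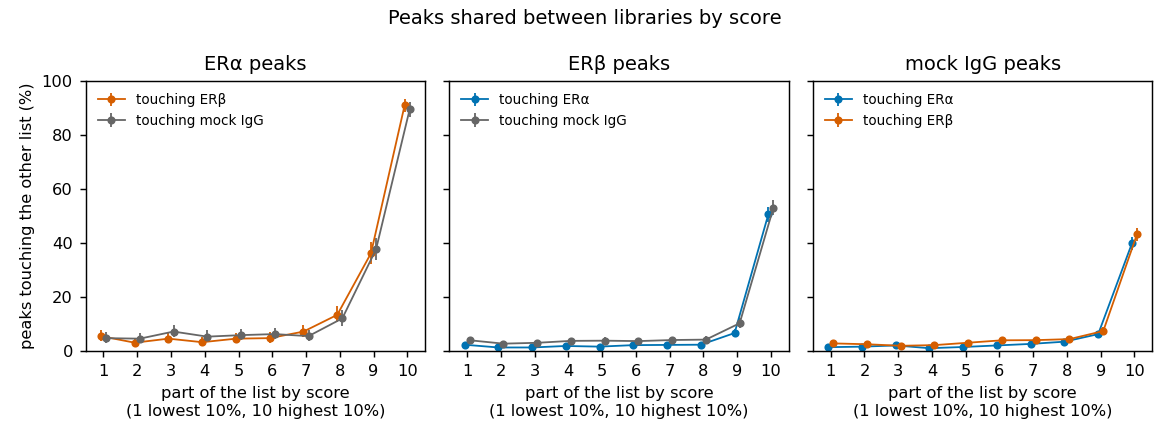
Share of peaks touching another list, in percent, for each of 10 equal parts of a list ordered by the authors' score; points are shares and bars are 95% exact binomial intervals. The receptor lists and the mock list rise together, and the top 10% of ERα peaks touches ERβ at 91.2% and mock at 89.7%. The parts differ between lists in peak number and score range.

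Strong receptor peaks were nearly all present in the mock list. Of the 359 strong ERα peaks, 347 (96.7%) touched a mock peak and 345 (96.1%) an ERβ peak. Of the 341 strong ERβ peaks, 332 (97.4%) touched a mock peak and 335 (98.2%) an ERα peak. Of the 308 strong mock peaks, 298 (96.8%) touched an ERα peak and 303 (98.4%) an ERβ peak. A strong ERα peak was not found more often in the ERβ list than in the mock list: 6 touched ERβ alone and 8 touched mock alone (exact McNemar test, p = 0.791, adjusted p = 0.791 over the 3 lists). For strong ERβ peaks, 7 touched ERα alone and 4 touched mock alone (exact McNemar test, p = 0.549, adjusted p = 0.791). For strong mock peaks, 2 touched ERα alone and 7 touched ERβ alone (exact McNemar test, p = 0.180, adjusted p = 0.539). These tests were added after the data were seen and treat neighbouring peaks as independent.

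Of the 5 highest peaks of each list, most lay at the same loci. The highest ERα and ERβ peak lay on chromosome 1 at 55701024 to 55706505, with a score of 3206 in the ERα list, 3180 in the ERβ list and 2651 in the mock list. The mitochondrial genome carried a peak spanning positions 1 to 10449 in the ERα list, with a score of 3100 in each list. A peak on chromosome 13 at 33502335 to 33505598 also had a score of 3100 in each list. That exact value stands at 3 ERα, 3 ERβ and 2 mock peaks, so equal scores there were not read as equal signal. Chromosome 3 at 41455 to 42126 scored 3100 in both receptor lists and 2917 in the mock list, and chromosome 12 at 1508642 to 1511273 scored 2271 for ERα, 2570 for ERβ and 2177 for mock. The mock list also had among its 5 highest peaks chromosome 1 at 56023604 to 56032677, with a score of 2297. Receptor peaks touching it scored up to 2121 for ERα and 2310 for ERβ.

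Strong peaks were also clustered along the genome. In the 1-Mb window of chromosome 1 that starts at 180000001 there were 50 ERα, 56 ERβ and 55 mock peaks, of which 35, 34 and 34 were strong. The window of chromosome 1 from 55000001 held 56 ERα, 56 ERβ and 50 mock peaks. The window of chromosome 16 from 21000001 held 45, 50 and 52. The 77 windows with 20 or more mock peaks of any score held 18.0% of all ERα peaks and 64.6% of strong ones. For ERβ these windows held 11.3% of all peaks and 63.3% of strong ones, and for mock, by whose peaks they were chosen, 12.9% and 67.5%.

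**Figure D2:**
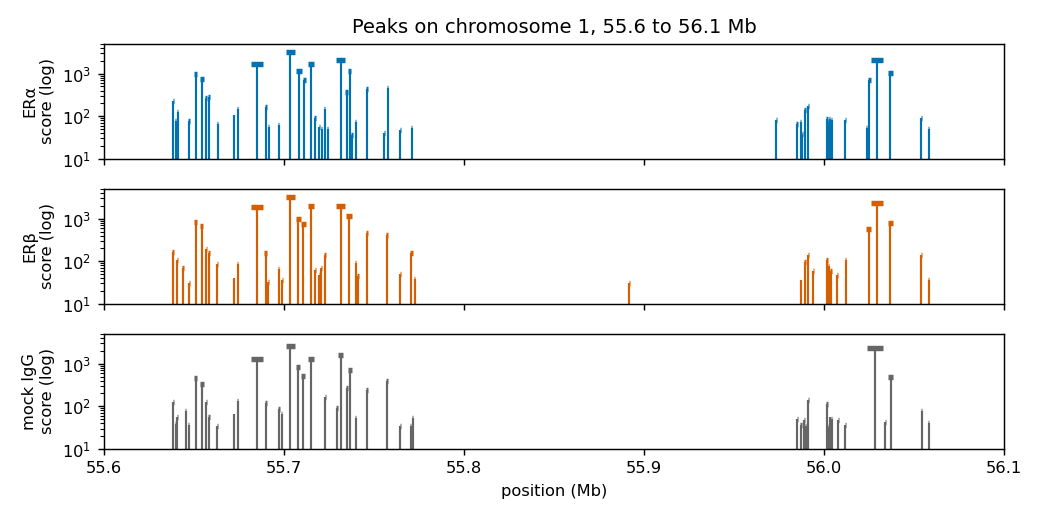
Peaks on chromosome 1 between 55.6 and 56.1 Mb, with position in Mb on the horizontal axis and the authors' score on a log axis; horizontal strokes show peak widths to scale, with 1 panel per library. The region holds 51 ERα, 49 ERβ and 47 mock peaks at largely matching positions.

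Some regions were shared by both receptors and lacked a mock peak. A total of 207 ERα peaks touched an ERβ peak when neither peak touched the mock list, and 85 of them (41.1%) lay in windows with 20 or more mock peaks. Both scores reached 50 at 35 of the 207 loci (16.9%) and 100 at 2. The corresponding loci of ERα with mock outside ERβ reached 50 at 21 of 242 (8.68%) and 100 at 0, and those of ERβ with mock outside ERα at 33 of 454 (7.27%) and at 1. Outside windows with 20 or more mock peaks the shares reaching 50 were 14.8% for both receptors, 8.13% for ERα with mock and 5.38% for ERβ with mock. These shares were compared by Fisher's exact test after the data were seen. Some of its p-values were below 0.05. They are not given, because the limit of 50 need not mark the same signal in each list. The chromosome 10 tests at that limit, given further below, share this weakness. The highest by rank was chromosome 1 at 54959836 to 54961020, with a score of 136 for ERα and 153 for ERβ and the nearest mock peak 2165 bp away. Next came chromosome 16 at 22126536 to 22127039, with scores of 105 and 170 and a mock peak 2190 bp away. Others of the leading 10 were chromosome 1 at 99033812 to 99035011, with a mock peak 108 bp away, chromosome 2 at 137391239 to 137392111, chromosome 9 at 12170503 to 12171298 and chromosome 14 at 22021328 to 22022821. Chromosome 1 at 11912722 to 11913213, chromosome 20 at 27462604 to 27463211 and chromosome 14 at 21685882 to 21686703 completed the list together with chromosome 9 at 4408462 to 4409003. The last of these lay 135589 bp from the nearest mock peak, further than any other of the 10. Of the 207 loci, 49 had a mock peak within 1 kb and 134 (64.7%) within 10 kb. Closeness to the absent list was also common in the other pairs. Of the 242 loci of ERα with mock, 137 (56.6%) had an ERβ peak within 10 kb. Of the 454 loci of ERβ with mock, 206 (45.4%) had an ERα peak within 10 kb.

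Outside the mock list, 207 of 4385 ERα peaks (4.72%, exact binomial interval 4.11 to 5.39) touched an ERβ peak, 9.09-fold above random placement. Outside the ERβ list, 242 of 4413 ERα peaks (5.48%, 4.83 to 6.20) touched a mock peak, 8.14-fold above placement. The ratio of these excesses was 1.12, with a 95% block bootstrap interval of 0.918 to 1.35 that includes 1; with a reciprocal overlap of 50% it was 1.21 (1.01 to 1.45). Seen from the ERβ list, the excess was 9.26-fold with ERα outside mock and 5.78-fold with mock outside ERα, a ratio of 1.60 (1.34 to 1.88). With lists shortened to 5347 peaks by score, that ratio was 1.27 (0.978 to 1.65), and at a score of 50 or more it was 3.94 (2.82 to 5.48), where the ratio from the ERα list was 0.896 (0.661 to 1.22). Each of the 4 placement tests had a permutation p of 0.001998, the smallest possible. These comparisons were added after the data were seen.

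The lists were next compared by chromosome. Chromosome X carried far fewer peaks than its share of sequence in every list. It held 27 ERα peaks, 55 ERβ peaks and 57 mock peaks, which is 0.508%, 0.433% and 0.363% of peaks on autosomes and X, while X made up 5.76% of the sequence between chromosome start and furthest peak. The ratio of observed to expected share was 0.0882 for ERα (exact binomial interval 0.0582 to 0.128), 0.0753 for ERβ (0.0567 to 0.0979) and 0.0630 for mock (0.0478 to 0.0816). The two-sided exact binomial test gave p = 1.86e-97 for ERα, 1.82e-241 for ERβ and 1.79e-311 for mock, values that treat clustered peaks as independent. At a score of 50 or more the ratios were higher but still below 1, at 0.206 for ERα (0.107 to 0.358), 0.194 for ERβ (0.0969 to 0.345) and 0.153 for mock (0.0764 to 0.273). Against the X share of the mock list, neither receptor was lower on X: the ratio was 1.40 for ERα (exact binomial p = 0.166) and 1.19 for ERβ (p = 0.392). ERα and ERβ differed on X by 0.0746 percentage points (Newcombe interval -0.131 to 0.326, Fisher's exact p = 0.544).

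**Figure D3:**
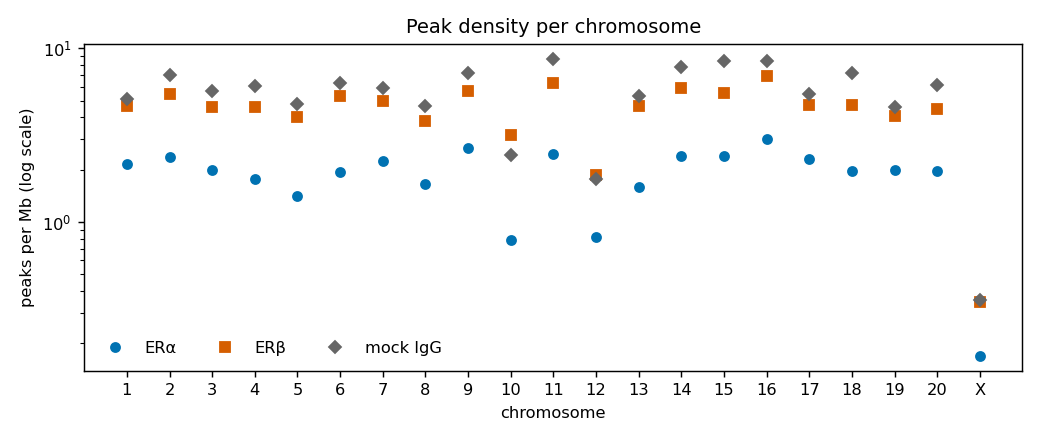
Peaks per Mb on each autosome and on X, on a log axis, with 1 point per list; lengths are the furthest peak end over all lists. Chromosome X lies below every autosome in all 3 lists, at 0.169 ERα, 0.344 ERβ and 0.357 mock peaks per Mb.

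Among autosomes, chromosomes 10 and 12 had the lowest densities. ERα was lowest on chromosome 10, at 0.791 peaks per Mb, while ERβ and mock were lowest on chromosome 12, at 1.87 and 1.77. Chromosome 16 was highest for ERα and for ERβ, the latter at 6.88, and chromosome 11 was highest for mock, at 8.69. The autosome medians were 1.99, 4.68 and 5.99 peaks per Mb.

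Chromosome 10 differed in share between the lists. It held 354 ERβ peaks (2.78%), 272 mock peaks (1.73%) and 89 ERα peaks (1.66%). The odds of a chromosome 10 peak were 1.63 times higher in the ERβ list than in the mock list (interval 1.39 to 1.91, Fisher's exact test, adjusted p = 4.35e-08 over 22 chromosomes and scaffolds). The odds in the ERα list relative to ERβ were 0.592 (0.468 to 0.748, Fisher's exact test, adjusted p = 0.000118). In the upper 50% of each list by its own score the ERβ excess over mock held, with an odds ratio of 1.52 from 151 and 124 peaks (Fisher's exact p = 0.00073). At a score of 50 or more the excess was not present. Chromosome 10 held 4 such ERβ peaks and 16 such mock peaks, with an odds ratio of 0.312 (Fisher's exact p = 0.0394, unadjusted). This limit was chosen after the data were seen and need not mark the same signal in each list. The difference between ERβ and ERα was not detectable at that limit, with 4 and 3 peaks and an odds ratio of 1.37 for ERβ against ERα (Fisher's exact p = 0.723). ERα against mock gave 3 higher and 3 lower of 22, and ERβ against mock gave 2 higher and 2 lower.

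In 1-Mb windows, ERβ and mock did not differ in any of 1198 windows by Fisher's exact test after adjustment, with 68 windows at an unadjusted p under 0.05. ERα had a higher share of its peaks than mock in 10 of 799 windows and a lower share in 0, with 58 at an unadjusted p under 0.05, and 9 of the 10 were windows with 20 or more mock peaks. ERα had a higher share than ERβ in 4 of 583 windows and a lower share in 0, with 40 at an unadjusted p under 0.05, and all 4 were windows with 20 or more mock peaks. A locus called in every list takes a higher share of the shortest list, so these counts do not show more ERα peaks: the windows of chromosomes 1 and 16 named above held similar peak numbers in the 3 lists.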

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

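The tests below were all chosen after the result was seen, apart from the exact test of the share of peaks on X. On 1 chromosome and 1 scaffold the ERα and ERβ lists differed in a test of the difference itself: the odds of a peak on chromosome 10 in ERα against ERβ were 0.592, and the odds on scaffold KL568458.1 were 3.71, from 14 ERα and 9 ERβ peaks (Fisher's exact test, adjusted p = 0.0231 over 22 chromosomes and scaffolds). The scaffold odds compare shares of lists of unequal length and do not show a difference between the receptors: the mock list had 13 peaks there, and 1 ERβ peak touched 3 ERα peaks. At a score of 50 or more, the chromosome 10 difference between ERβ and ERα was no longer past the threshold, with odds of 1.37 from 4 and 3 peaks (Fisher's exact p = 0.723), while it held at 1.94 in the upper 50% by score from 151 and 33 peaks (p = 0.000411), 1.54 among unmatched peaks (p = 0.000261) and 1.56 outside dense windows (p = 0.000132). Sharing with mock and the few peaks on X are weighed as patterns common to both receptors.

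The ERβ list held a larger share of chromosome 10 peaks than either other list, an excess over mock that held in the upper 50% by score (odds 1.52) and turned to 0.312 at a score of 50 or more, with 4 ERβ and 16 mock peaks (Fisher's exact p = 0.0394). A few loci on chromosome 10 as the cause are argued against by odds of 1.49 against mock without the 5 windows of largest ERβ excess (Fisher's exact p = 1.53e-06). An ERβ library less biased against chromosomes of low density could also raise the share. Over the other 19 autosomes, Spearman's rho between ERα density and the ERβ to mock density ratio was -0.393 (permutation p = 0.0955, Pearson r -0.511 with p = 0.0281), and over all 20 it was -0.480 (permutation p = 0.0328), while r fell from -0.674 to -0.199 without chromosomes 10 and 12, on which it rests. That explanation stays open because few chromosomes carry it, and no biological explanation was tested.

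Receptor peaks and the mock list coincide at the strongest loci. If the strongest ERα peaks marked binding that the mock library lacks, few of them would touch a mock peak, and 89.7% of the top 10% did. Sites bound by both receptors beyond what a receptor shares with mock would raise sharing in both directions. From the ERα side the ratio was 1.12 (0.918 to 1.35), 1.21 (1.01 to 1.45) with reciprocal overlap and 0.896 (0.661 to 1.22) at a score of 50 or more, and from the ERβ side it was 1.60 (1.34 to 1.88), 1.27 (0.978 to 1.65) with equal list sizes, 2.25 (1.70 to 2.88) in the upper 50% by score and 3.94 (2.82 to 5.48) at a score of 50 or more. Both sides rest on the same 207 loci and differ through the sharing with mock, 8.14-fold for ERα and 5.78-fold for ERβ. The ERα interval includes 1 at an overlap of 1 bp. In some other settings the ERα ratio lies below 1, with intervals that include 1. Sharing by both receptors beyond that with mock therefore stays open.

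Few peaks on chromosome X were found in all 3 lists. Receptors avoiding X as the cause of the common pattern is argued against by the mock list, whose ratio was 0.0630. Whether the receptors avoid X in addition cannot be told from the mock list. If male germ cells on average held about 0.5 copies of X per autosome copy, and peak number were proportional to copies, the ratio would be about 0.5. The highest upper bound was 0.128 over the full lists and 0.358 over peaks of score 50 or more. These bounds treat clustered peaks as independent. Calls near the score floor that fall away steeply with local read depth may contribute: the odds of X were 2.78 among mock peaks of score 50 or more against the rest (Fisher's exact p = 0.00476), but 1.11 (p = 0.783) without the windows at 36 and 73 Mb, and 2.92 (p = 0.0917) at a score of 100 or more, a test run first. Windows were taken out on X alone, and autosomal windows rich in strong peaks were kept. Taking them out lowers the odds whatever the cause, so the fall to 1.11 decides nothing. This stays open, since the odds rest on few peaks: 11 mock peaks of score 50 or more lay on X, and 4 without those windows. All 3 mock peaks on X with a score of 100 or more lay in those windows.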

How the results depend on the processing

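Tests at a score of 50 or more or of 100 or more, within 250 kb, outside dense windows, with equal list sizes, and all those of sharing ratios and of chromosome 10 were chosen after the result was seen. Each of the 3 overlap results kept its direction and its side of the threshold in all 10 alternatives, with excesses from 8.01 to 76.1 for ERα with ERβ, 7.45 to 73.7 for ERα with mock and 5.76 to 74.1 for ERβ with mock. Peak numbers moved with the score limit, to 1036 ERα, 1008 ERβ and 1269 mock peaks at 50 or more, and to 359, 341 and 308 at 100 or more. The ratio of ERα sharing was 1.21 and past its threshold with reciprocal overlap. It was 0.974 (0.818 to 1.15) within 1 kb, 0.996 (0.782 to 1.25) outside dense windows and 0.896 (0.661 to 1.22) at a score of 50 or more. It stayed above 1 at 1.19 (0.918 to 1.53) in the upper 50% by score and 1.13 (0.929 to 1.36) on placed chromosomes. With placement within 250 kb it was 1.21 (0.998 to 1.47), and with equal list sizes 1.05 (0.813 to 1.35). Apart from reciprocal overlap, all these intervals include 1, so no change of direction was shown. The ratio of ERβ sharing fell to 1.27 with equal list sizes, and was 2.25 in the upper 50% by score and 3.94 at a score of 50 or more. The X ratio rose to 0.206 for ERα, 0.194 for ERβ and 0.153 for mock at a score of 50 or more, still past its threshold. With the mock share as the expectation, the X ratio turned to 1.40 for ERα and 1.19 for ERβ, which follows from the low mock share. At a score of 50 or more the chromosome 10 odds turned to 0.312 for ERβ against mock and, with few peaks left, were 1.37 and no longer past the threshold for ERβ against ERα. Apart from these, the cause was not tested. The difference between ERα and ERβ on X kept its side in both alternatives. Promoter, response element, repeat and gene list results and their alternatives were not run. Expectation from the mock share does not apply to the mock list itself. Unknown depth and an unknown cutoff in calling limit every comparison of list lengths.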

Other observations

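The regions below were named after their values were seen, and no test was run on them. Of the strong ERα peaks, 12 touched no mock peak, and 9 of these had a mock peak within 10 kb. Those far from mock were on chromosome 5 at 154035176 to 154035932, with a score of 109 and the nearest mock peak 904592 bp away, and on chromosome 1 at 197983228 to 197984332, with a score of 108 and the nearest mock peak 517563 bp away, and neither touched an ERβ peak. Another lay on scaffold KL568245.1 at 11 to 428 with a score of 227. Of the strong ERβ peaks, 9 touched no mock peak, headed by scaffold KL568273.1 at 2080 to 3180 with a score of 252. Of the strong mock peaks, 3 touched neither receptor list.

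The few strong peaks on X, 4 for ERα, 6 for ERβ and 3 for mock, lay at 2 places in all 3 lists. The mock list had its strong X peaks at 36469413 to 36470373, 73074602 to 73076104 and 73089177 to 73091351, with scores of 243, 196 and 478. The highest-scoring ERα peaks at these places were at 36469397 to 36470409, with a score of 588, and 73089291 to 73091381, with a score of 557. Those of ERβ were at 36469276 to 36470504, with a score of 455, and 73089286 to 73091364, with a score of 511. Chromosome Y carried 3 ERα, 2 ERβ and 3 mock peaks, and the mitochondrial genome carried 2 in each list.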
